A study of Homo sapiens with 2 samples.

How the data were processed

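Single-cell RNA libraries were made from mammospheres of MDA-MB-231, an established triple-negative breast cancer line of mesenchymal character. Per the labels' protocols, cells were first adapted for 30 days as flat cultures in high-glucose medium, without metformin or at a dose of 2 mM. The adapted cells were then grown as mammospheres, floating spheres that form on low-attachment plates, for 10 days and taken apart with trypsin and EDTA. Metformin is a biguanide used against type 2 diabetes and is known to inhibit respiratory chain complex I. The labels give 1 library per dose, so there were no replicates. Per the labels' protocols, cDNA was amplified on the capture beads and libraries were made with the Nextera XT kit.

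The authors deposited whole counts of unique molecular identifiers (UMIs, the random tags that mark single captured transcripts) for 19826 genes in 2000 barcodes, 1000 of each library. The submitters' processing notes name bcl2fastq, STAR 2.5.0a and the genome build hg19. How barcodes were selected, how UMIs were collapsed, which annotation was used and whether counting used strand are not given in the sources used here. Genes that share sequence with a close relative or a processed copy, and genes that overlap another, therefore carry uncertain counts. No coordinates are given, since the reference at hand was of another build than hg19. All 2000 columns of the table were mapped to a library by the name they start with.

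Barcodes with at least 500 UMIs and 300 genes were kept as cells. This kept 1000 barcodes of the 0 mM library and 991 of the 2 mM library. No doublet caller was run, because most doublets within 1 cell line join like cells; the 5% of barcodes with the most UMIs were left out in an alternative. Counts were summed over the cells of each library and divided by the library total and scaled to a common total, giving CPM. The ratio of CPM at 2 mM over 0 mM was computed for genes with at least 50 CPM in either library and at least 50 UMIs over both. Its 95% interval is the exact conditional Clopper-Pearson interval. Single sums have exact Poisson intervals and shares of cells exact binomial intervals. The interval of a difference between shares joins the outer bounds of the 2 separate share intervals, so it is wider than a 95% interval. All of these intervals cover counting error only, and not differences between cultures or library preparations. Intervals of sums and ratios treat each UMI as a separate draw, so they also leave out the spread between cells and are too narrow. A sum of 3 counts corresponds to 0.681 CPM in the 0 mM library and 0.919 CPM in the 2 mM library.

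With 1 library per dose no test was run and no p-value is given. Genes are described as higher or lower by size, at a ratio of at least 1.5 either way. On counts simulated from the real means and totals of the 2 libraries, with 200 genes set to a known fold, the interval covered the true fold of 97.0% of those genes. It covered a ratio of 1 in 95.2% of 3753 unaltered genes, and 0 of these passed 1.5-fold. The simulated sums were Poisson counts, the model that the interval assumes. The simulation therefore checks the computation only and gives no rate of falsely high or low genes in the real libraries.

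The 28 gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. Of each list, the members that passed the minimum were used, and the list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on CPM. This percentile describes these 2 libraries and is not a test. The interval given with a list's median is a binomial interval over its genes. Named genes are the 12 with the highest and the 12 with the lowest ratio, ranked by the interval bound nearest 1. Mitochondrially encoded genes, ribosomal protein genes and pseudogenes of those were left out of this ranking. Also named are up to 3 members with the highest and up to 3 with the lowest ratio of each list, the genes of the metformin list and the cell type markers. Any other gene is named with the remark that it was chosen after its values were seen.

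For shares of cells, each cell was thinned at random to 1000 UMIs and shallower cells were left out, 56 of the 0 mM and 191 of the 2 mM library. A cell was counted as carrying cycle transcripts at 3 or more UMIs of the S-phase or the G2/M list. The cells of both libraries were clustered jointly on 2000 variable genes and 20 principal components with 15 neighbours and Leiden clustering at resolution 0.5. Leading genes of a cluster were those with the highest ratio of CPM (plus 5) inside over outside, among genes of at least 100 CPM inside. Where both libraries had enough cells in the cluster, this CPM was the mean of their values. A cluster was named when at least 3 of a type's markers were among its 50 leading genes.

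Alternatives planned before the data were examined were all deposited barcodes, a minimum of 1000 UMIs, at most 10% mitochondrial UMIs, cells weighted equally, and cells with at most 1 UMI of the cycle lists. Others were scaling with edgeR TMM factors, scaling without mitochondrial and ribosomal protein genes, CPM minimums of 20, 100 and none, other thinning depths and other clustering settings. Alternatives chosen after seeing the data left out the cluster led by mitochondrial ribosomal RNA, barcodes ending in an uncalled base, or the interferon-like clusters. Values inside single clusters with at least 50 cells of each library were also added after seeing the data. Further alternatives of that kind merged barcodes that lie 1 base apart, raised the number of cycle UMIs to 10, or counted interferon cells by 5 or more marker UMIs. Of the 10 surface and stem cell markers planned for shares of cells, 6 were analysed here. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, leidenalg 0.10.2 and python-igraph 0.11.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors only. Results of some genes are not reported.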

Results

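The study compared the transcriptomes of MDA-MB-231 mammospheres whose cells had been adapted to culture with 2 mM metformin or without it, as its design text states. The 0 mM library held 1000 cells with 4403045 UMIs, a median of 3386 UMIs and 1745.5 genes per cell. The 2 mM library held 991 cells with 3264343 UMIs, a median of 2509 UMIs and 1454 genes per cell. Mitochondrially encoded transcripts took 5.49% and 5.38% of the UMIs, and ribosomal protein transcripts 9.53% and 9.79%. In both libraries many barcodes lay 1 base apart from another barcode. Merging such barcodes left 931 cells at 0 mM and 883 at 2 mM, with no effect on summed counts. Each dose had 1 library, so no difference below has a replicate check, and all intervals cover counting error only.

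Cells adapted to 2 mM metformin had higher levels of single genes such as DEFB1, LCN2 and CDH11, and lower levels of ID1, ID3, ACTB, VIM and some genes of the G2/M list. The antimicrobial peptide DEFB1 (2.73 CPM at 0 mM and 71.7 CPM at 2 mM) and the iron-siderophore binder LCN2 (22.9 and 187 CPM) were among the genes with the highest ratios. ID3 (180 and 23.3 CPM) and ID1 (413 and 114 CPM), which block DNA binding of basic helix-loop-helix factors, were among those with the lowest. Of 4105 genes compared, 207 were at least 1.5-fold higher and 136 at least 1.5-fold lower at 2 mM. At least 2-fold, 49 were higher and 23 lower. The remaining 91.6% of genes lay within 1.5-fold. This split depended on the scaling: with TMM factors 140 genes were at least 1.5-fold higher and 223 lower.

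The highest ratio belonged to DEFB1 at 26.3 (14.8 to 51.6), from 12 UMIs at 0 mM. CDH11, a cadherin of mesenchymal cells, had a ratio of 11.2 (7.15 to 18.2), and the transcription factor SOX4 and LCN2 had ratios of 8.19 (5.91 to 11.6) and 8.17 (6.61 to 10.2). The carboxypeptidase gene CPVL followed at 5.22 (4.40 to 6.22) and GCHFR, a feedback regulator of tetrahydrobiopterin synthesis, at 3.82 (3.14 to 4.67). The acute phase gene SAA2 had 302 CPM at 0 mM and 975 CPM at 2 mM, a ratio of 3.23 (3.03 to 3.45). The class II antigen presentation gene HLA-DRB5 had a ratio of 3.90 (3.03 to 5.07) and the neutrophil-attracting chemokine CXCL1 one of 2.93 (2.70 to 3.18). PDZK1IP1 (3.66), the adhesion receptor GPR116 (3.20) and the tetraspanin CD81 (3.19) complete the 12 highest. SAA2 and HLA-DRB5 have close relatives, SAA1 and HLA-DRB1, so the division of reads among them is uncertain. CDH11 moved from a log2 ratio of 3.48 to 4.38 when cells were weighted equally. In the cells with few cycle transcripts, the log2 ratio of CPVL was 1.07 against 2.38, that of SOX4 2.22 against 3.03, that of PDZK1IP1 1.41 against 1.87 and that of CXCL1 0.88 against 1.55. It was larger for HLA-DRB5 (2.89 against 1.96), LCN2 (3.65 against 3.03), GCHFR (2.39 against 1.93) and CD81 (1.99 against 1.67).

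**Figure D1:**
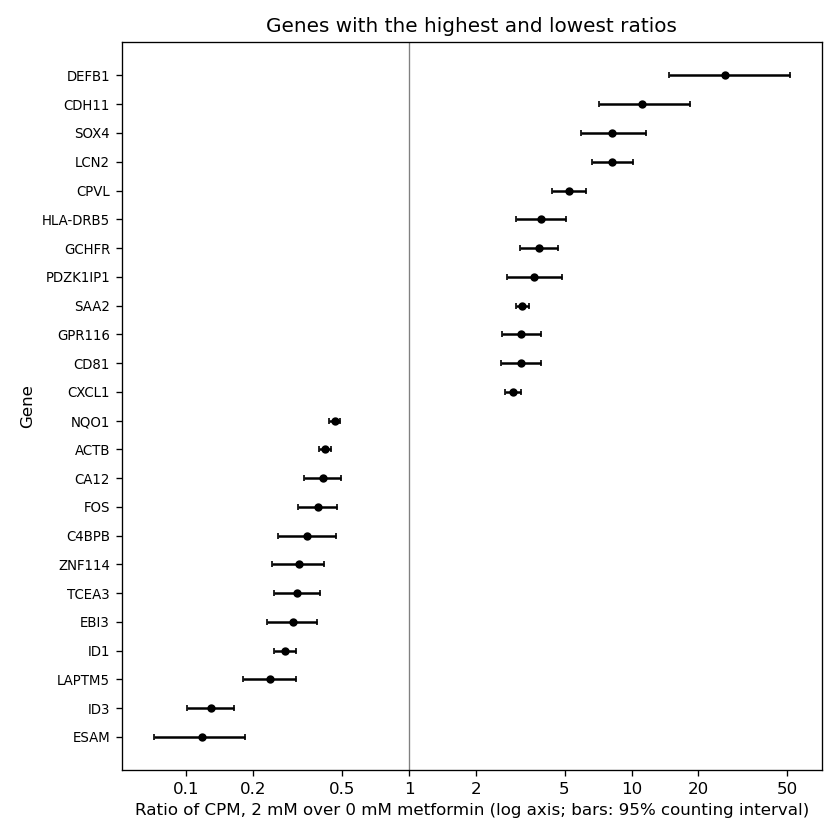
Ratio of CPM at 2 mM over 0 mM metformin (log axis) for the 12 genes with the highest and the 12 with the lowest ratios. Points are ratios of summed counts of 1 library each and bars are 95% counting intervals; DEFB1 lies highest at 26.3 and ESAM lowest at 0.117.

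At the other end, the junction adhesion gene ESAM had a ratio of 0.117 (0.0711 to 0.183), ID3 one of 0.129 (0.101 to 0.164) and ID1 one of 0.277 (0.247 to 0.310). The lysosomal membrane gene LAPTM5 (0.238), the cytokine subunit gene EBI3 (0.300), TCEA3 (0.315), ZNF114 (0.320) and C4BPB (0.349) were also lower. So were the immediate early gene FOS, at 101 and 39.5 CPM, and the carbonic anhydrase gene CA12, at 109 and 44.4 CPM. The quinone reductase gene NQO1 had 1025 and 476 CPM, and the actin gene ACTB 940 and 396 CPM, with ratios of 0.465 (0.438 to 0.492) and 0.421 (0.396 to 0.449). LAPTM5 moved from a log2 ratio of -2.07 to -2.83 without interferon-like clusters, and ZNF114 from -1.64 to -2.31 in the cells with few cycle transcripts. ACTB has many processed copies and its counts are uncertain for that reason.

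Most of the 24 genes differed in the same direction inside the 4 clusters compared. They were chosen for their ratios over these same cells, so agreement within parts of those cells is no separate support. In interferon-like clusters, in G2/M-like clusters and in all other clusters, each pooled, 12 of the 12 highest genes had ratios above 1. The 12 lowest genes all had ratios below 1. At least 1.5-fold, 12 of the highest were higher in each group. Of the lowest, 11 were at least 1.5-fold lower in G2/M-like clusters and 12 in the interferon-like and the other group. The interferon-like and the other group hold different clusters in each library, so these pooled values also compare unlike cells. A comparison inside the 4 single clusters with at least 50 cells of each library was added after seeing the data. In clusters 1, 2 and 3, all 12 highest genes had ratios above 1, and 11 in cluster 5. At least 1.5-fold, 10, 12, 12 and 11 of them were higher in clusters 1, 2, 3 and 5. Of the 12 lowest, 11 had ratios below 1 in clusters 1 and 5 and 12 in clusters 2 and 3. At least 1.5-fold, 10, 10, 11 and 11 of them were lower in clusters 1, 2, 3 and 5. LCN2 had 47.4 and 201 CPM in cluster 1, 35.1 and 290 CPM in cluster 2, and 17.2 and 68.3 CPM in cluster 3. ID3 had 174 and 32.7 CPM, 174 and 8.22 CPM, and 251 and 22.8 CPM in the same order. Genes of the opposite direction were CA12 in cluster 1, at 46.0 and 53.3 CPM, and 2 in the shallow cluster 5. These 2 were CXCL1, with 18 and 8 UMIs (155 and 112 CPM), and C4BPB, with 3 UMIs in each library (25.9 and 42.1 CPM). Nearly level were CA12 in cluster 3 (56.5 and 54.4 CPM) and LAPTM5 in cluster 2 (51.8 and 47.0 CPM). CA12 led cluster 7, which held 101 and 4 cells and was not compared. Counts in cluster 5 were low, such as 0 and 4 UMIs of DEFB1 and 1 and 2 UMIs of HLA-DRB5.

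Over all cells, G2/M genes were lower in the 2 mM library. All 43 compared members had ratios below 1 and 12 were at least 1.5-fold lower. Among these were CDCA3 (0.472), KIF2C (0.523), PSRC1 (0.525) and UBE2C (0.595), which act in mitotic entry, chromosome movement or anaphase. The mitotic cyclin gene CCNB1, a marker outside this list, had 266 CPM at 0 mM and 121 CPM at 2 mM. The median log2 ratio was -0.44 (-0.55 to -0.33), below all 10000 random lists (percentile 0), and lay at -0.20 without the 5% of barcodes with the most UMIs. The S-phase list had a median of -0.08 (percentile 13.3), with TYMS at 0.743, CDC6 at 0.610 and MCM6 at 1.21. In the cells with few cycle transcripts, which are picked by these lists, log2 ratios were -1.47 for TYMS against -0.43 and -0.99 for MCM6 against 0.28. For CCNB1 the log2 ratio there was -0.09 against -1.14.

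The cycle lists did not differ alike in all groups of cells. The G2/M median was 0.11 in the pooled interferon-like clusters, with 27 of 43 genes above 1, -0.35 in the G2/M-like cluster and -1.56 in the pooled other clusters. Inside single clusters it was -0.05 in cluster 1, with 20 genes above 1, -0.35 in clusters 2 and 3, and -0.48 in cluster 5. The positive pooled value was therefore not found inside cluster 2, which held most interferon-like cells at 2 mM. The S-phase median was 0.21 in the G2/M-like cluster, with 17 of 19 genes above 1, and -0.77 in the pooled other clusters, with 0 above 1. Inside clusters 1, 2 and 5 it was -0.13, -0.28 and -0.41.

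The list of oxidative stress genes under the transcription factor NRF2 had a median log2 ratio of -0.35 (percentile 0.02). Of its 16 members, 12 had ratios below 1, though only NQO1 and the metallothionein gene MT1X (0.663) passed 1.5-fold. MT1X was slightly above 1 in the cells with few cycle transcripts. The autophagy receptor gene SQSTM1 had a ratio of 0.697, and TALDO1, ME1 and FTH1 lay between 1.03 and 1.10. The list named nuclear-retained long RNAs had a median of -0.48 (4 genes, percentile 0.19). Its low median rests on MALAT1, GAS5 (0.735) and SNHG1 (0.703). Whether GAS5 and SNHG1 transcripts stay in the nucleus was not tested, so the name is only that of the list. MALAT1 took 2.42% of UMIs at 0 mM and 1.70% at 2 mM, whereas NEAT1 had a ratio of 1.24. NF-kB and inflammatory genes had a median of 0.27 (11 genes, percentile 99.4), with LCN2 and CXCL1 past 1.5-fold, CXCL2 at 1.42, and SOD2 at 0.810. Within groups of cells this median was smaller, at 0.11, 0.14 and 0.08 in the pooled interferon-like, G2/M-like and other clusters. Inside single clusters it was -0.06 in cluster 1, 0.56 in cluster 2, 0.14 in cluster 3 and 0.04 in cluster 5. Mitochondrial ribosome and import genes had a median of 0.12 (33 genes, percentile 97.9), with MRPS21 at 1.73 and HSPD1 at 1.53. These 5 lists were those whose medians lay outside the middle 95% of random lists, and for all of them but G2/M the interval over genes included 0.

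Over all cells, genes of energy metabolism, to which the respiratory target of metformin belongs, differed little as groups. Nuclear-encoded complex I genes had a median log2 ratio of 0.04 (34 genes, percentile 72.4), and 33 of them lay within 1.5-fold; NDUFB2 (1.76) was the exception. Nuclear-encoded genes of complexes II to V had a median of 0.08 (percentile 92.7), with all 37 within 1.5-fold. The 13 mitochondrially encoded genes had a median of 0.00 (percentile 59.6) and ran from MT-ND3 at 0.779 to MT-ATP8 at 1.48. Inside single clusters their median went both ways, at -0.28 in cluster 1, 0.02 in cluster 2, -0.15 in cluster 3 and 1.01 in the shallow cluster 5, with 13 of 13 genes above 1 there. With TMM factors the complex I median was -0.05, so its sign rests on the scaling.

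Glycolysis genes had a median of -0.07 (percentile 20.4) over members that went both ways. The pyruvate kinase gene PKM (1822 and 1023 CPM) and ENO2 (0.561) were lower, while PGAM1 (1.78) was higher and GAPDH lay at 0.734. Tricarboxylic acid cycle genes had a median of -0.15 (percentile 6.56), with MDH1 at 0.723. Cholesterol synthesis genes also had -0.15 (percentile 2.69), with SQLE at 1.48 and IDI1 at 0.680. Fatty acid synthesis genes had 0.12 (percentile 87.6), with the synthase gene FASN at 1.96 and ELOVL1 at 0.650, and fatty acid oxidation genes had -0.10 (percentile 14.6). These signs over all cells did not hold in every single cluster. In clusters 1, 2, 3 and 5, cholesterol synthesis had 0.31, -0.002, -0.12 and -0.14, and the tricarboxylic acid cycle 0.12, -0.03, 0.25 and -0.30. Fatty acid synthesis had 0.57, 0.16, 0.22 and -0.30, and fatty acid oxidation 0.21, -0.11, 0.07 and -0.59.

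**Figure D2:**
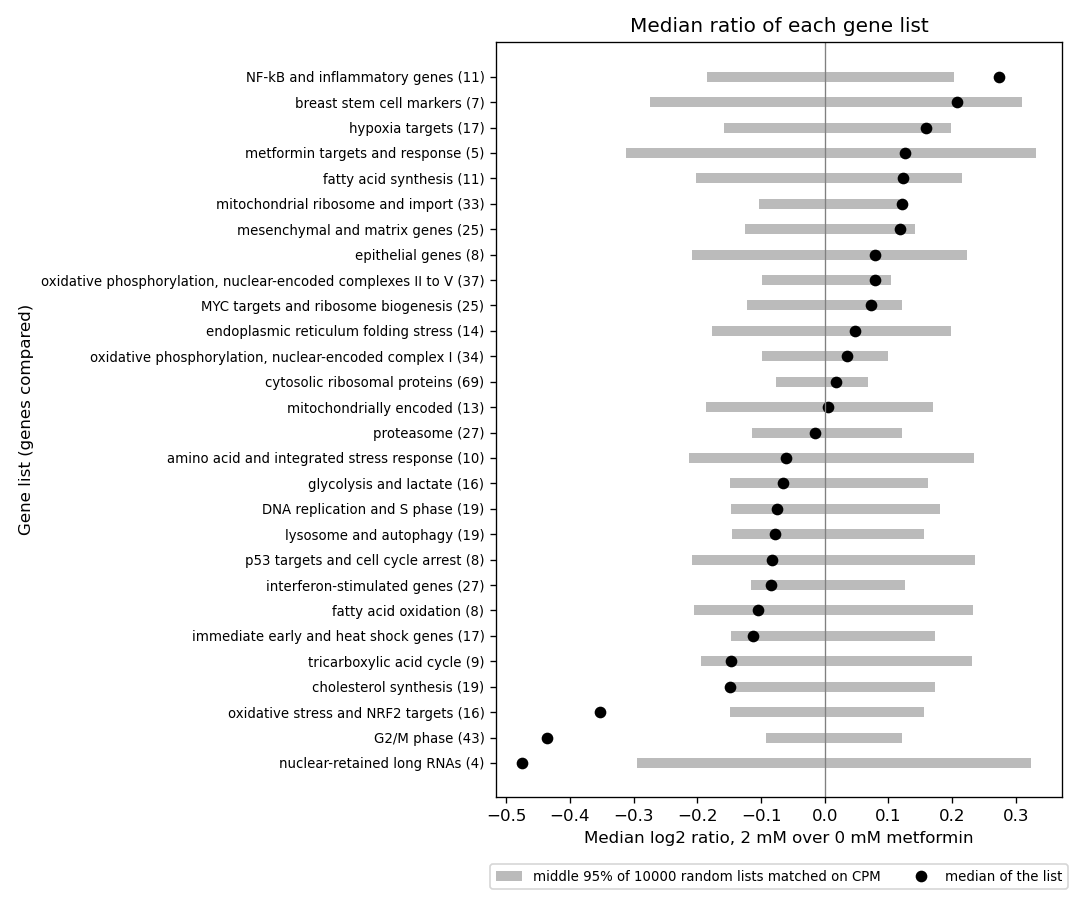
Median log2 ratio of CPM at 2 mM over 0 mM for each of the 28 gene lists (points), with the number of genes compared in brackets. Grey bars span the middle 95% of medians of 10000 random lists matched on CPM; the G2/M list lies at -0.44 and the NF-kB list at 0.27, both outside their bars.

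Of the genes known to respond to metformin or to carry or sense it, 5 passed the expression minimum. All 5 ratios lay above 1 and within 1.5-fold, with ATP6AP1 at 1.30, DICER1 at 1.16, DDIT4, a stress-induced mTOR inhibitor, at 1.09, PSENEN at 1.06 and TXNIP the lowest. The intervals of DICER1, PSENEN and TXNIP included 1, and the log2 ratio of DICER1 was 0.81 against 0.21 in the cells with few cycle transcripts. The list's median was 0.13 (percentile 77.3), 0.04 with TMM factors, which put TXNIP at a log2 ratio of -0.02 and PSENEN just below 0, and 0.39 with no CPM minimum. GDF15, a hormone raised by metformin in other settings, had 23.4 and 38.9 CPM, below the minimum for comparison. The transporter gene SLC22A3 had 29 and 15 UMIs. The kinase subunit genes PRKAA1 (35.4 and 48.4 CPM) and PRKAA2 (16.8 and 22.1 CPM) were also below the minimum. The integrated stress response list had a median of -0.06 (percentile 25.1), with WARS at 0.598 and DDIT3 at 0.720. PSAT1 was at 1.59, but below 1 in the cells with few cycle transcripts, where the log2 ratio of WARS was -1.63 against -0.74. The endoplasmic reticulum folding list had 0.05 (percentile 66.2; -0.04 with TMM factors).

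Mesenchymal and matrix genes split rather than moving together, with 5 of 25 at least 1.5-fold higher and 5 at least 1.5-fold lower (median 0.12, percentile 94.5). THBS1 (2.16) and S100A4 (2.11) were higher beside CDH11. VIM, the intermediate filament of mesenchymal cells, had 3271 CPM at 0 mM and 1596 CPM at 2 mM, a ratio of 0.488 (0.473 to 0.504). The transcription factor ZEB1 (0.587) and CTGF (0.546) were lower too, although CTGF was above 1 in the cells with few cycle transcripts. Over all cells, epithelial genes had a median of 0.08 (8 genes, percentile 77.2), none past 1.5-fold. Inside clusters 1, 2, 3 and 5 their median was larger, at 0.26, 0.44, 0.48 and 0.36, with 6, 6, 8 and 5 genes above 1. Breast stem cell markers had 0.21 (7 genes, percentile 91.0). Within this list SOX4 and the integrin gene ITGA6 (2.00) were higher and CD44, a hyaluronan receptor, had 372 and 262 CPM.

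Hypoxia targets had a median of 0.16 (percentile 94.6), with VEGFA (1.87), FAM162A (1.59) and EGLN1 (1.52) past 1.5-fold; the log2 ratio of EGLN1 was 1.38 against 0.60 in the cells with few cycle transcripts. The lists of p53 targets (-0.08, percentile 20.8), lysosome and autophagy (-0.08, percentile 13.7), proteasome (-0.01, percentile 39.7), and immediate early and heat shock genes (-0.11, percentile 6.29) lay within the random range. So did MYC targets (0.07, percentile 87.3) and cytosolic ribosomal proteins (0.02, percentile 81.2) over all cells. Inside clusters 1, 2, 3 and 5 the median of MYC targets was 0.23, 0.11, 0.20 and 0.33. That of ribosomal proteins was -0.32, -0.19, -0.11 and 0.07 in the same order, with 57, 48, 44 and 31 of 69 genes below 1. Single ribosomal protein genes stood apart, such as RPL3 at 2.49 and RPL10 at 2.20, but these have processed copies and their counts are uncertain. Markers of leukocytes other than CD74 (1.46), of fibroblasts and of endothelium were close to absent: PTPRC had 0 and 1 UMIs, COL1A1 5 and 3 UMIs.

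At 1000 UMIs per cell, a smaller share of cells carried cycle transcripts at 2 mM, but the size of this difference depended on depth and threshold. After thinning to 1000 UMIs, 56.8% (53.5% to 60.0%) of 944 cells at 0 mM and 47.5% (44.0% to 51.0%) of 800 cells at 2 mM had 3 or more G2/M UMIs. The mean was 6.19 and 5.03 G2/M UMIs per cell. For the S-phase list the shares were 34.3% (31.3% to 37.4%) and 27.5% (24.4% to 30.7%). For G2/M the difference was -9.28 points. It was -8.54 points (-14.4 to -2.61) at 500 UMIs, -7.31 points at 10% mitochondrial UMIs or less, -9.50 points without the 5% of barcodes with the most UMIs, -9.76 points for 2 or more and -8.97 points for 5 or more G2/M UMIs, and -13.6 points with barcodes merged, all with intervals below 0. The interval included 0 for -6.04 points (-12.4 to 0.33) at 2000 UMIs and -4.08 points (-9.04 to 0.96) for 10 or more UMIs, a threshold chosen after seeing the data. For S phase the difference was -6.82 points (-13.0 to -0.56), and it was -6.82 points without the 5% of barcodes with the most UMIs, -10.5 points (-17.1 to -3.71) for 2 or more UMIs and -8.63 points with barcodes merged, all with intervals below 0. Intervals that included 0 were found at -1.27 points (-5.83 to 3.30) at 500 UMIs, -4.12 points (-11.9 to 3.73) at 2000 UMIs, -5.25 points (-11.6 to 1.16) at 10% mitochondrial UMIs or less, -2.51 points for 5 or more UMIs and -0.79 points for 10 or more. Unthinned shares were 91.0% and 78.8% for G2/M and 76.6% and 57.9% for S phase. The threshold divides a range: 289 cells at 0 mM and 244 at 2 mM had 2 or 3 G2/M UMIs. Free RNA in the droplets adds to such counts, and no cell type lacking these transcripts was at hand to measure it.

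**Figure D3:**
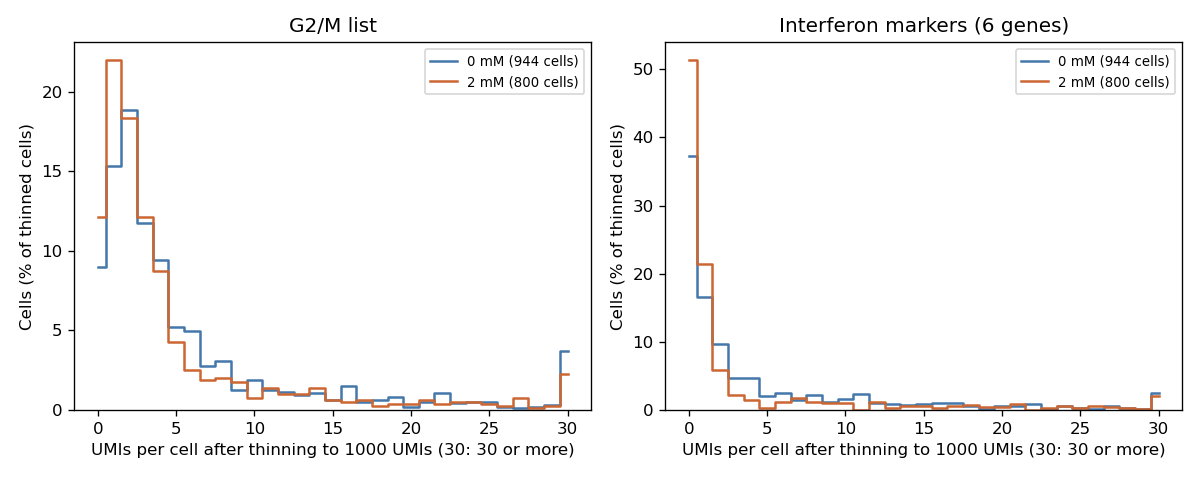
Distribution of UMIs per cell of the G2/M list (left) and of 6 interferon markers (right) in cells thinned to 1000 UMIs, as a percentage of the 944 cells at 0 mM and the 800 cells at 2 mM. The last step holds cells with 30 or more UMIs; mean G2/M UMIs were 6.19 at 0 mM and 5.03 at 2 mM.

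A UMI of CD44 was found in 29.3% (26.5% to 32.4%) of thinned cells at 0 mM and 19.6% (16.9% to 22.5%) at 2 mM. ITGA6 was found in 142 of the 944 cells (12.8% to 17.5%) and in 222 of the 800 cells (24.7% to 31.0%), in the direction of its CPM. Unthinned, CD44 was found in 65.0% and 41.9% of cells and ITGA6 in 39.7% and 49.8%. EPCAM was found in 2.97% and 3.75% of thinned cells and in 10.1% and 11.3% of unthinned cells, with overlapping intervals. ALDH1A3 was found in 1 and 3 thinned cells (0.700% and 1.92% of unthinned cells), and ALDH1A1 and SOX2 in 0 cells at 0 mM and 1 cell at 2 mM. With 0 of 944 cells, the share of such thinned cells with a UMI is at most 0.390%. This does not bound the share of cells that express these genes, since scarce transcripts are often missed at 1000 UMIs. Unthinned, ALDH1A1 was in 0 and 3 cells and SOX2 in 1 and 2 cells.

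Both libraries held cells with a strong interferon response beside cells without it. Joint clustering gave 7 clusters, of which clusters 2 and 6 were interferon-like. Cluster 2 was led by IFNL1, RSAD2, CCL5, OASL and CXCL10, and cluster 6 by GBP4, NOV and LTB with IFIT2 among its 10 leading genes. Together they held 29.2% (26.4% to 32.1%) of cells at 0 mM and 22.3% at 2 mM. Cluster 2 held 136 and 218 of these cells and cluster 6 held 156 and 3. Counted by at least 5 UMIs of the interferon markers after thinning, a rule chosen after seeing the data, the shares were 26.9% and 17.5%. At 500 UMIs they were 15.9% and 12.9%, a difference of -2.98 points (-7.43 to 1.48). Unthinned, they were 44.6% and 25.9%, and 64 and 15 thinned cells had 4 or 5 such UMIs. The summed interferon-stimulated list had a median of -0.08 (27 genes, percentile 8.05), with IFI27 at 2.83 and BST2 at 1.38 but ISG15 at 0.722 and IFI35 at 0.652. In the cells with few cycle transcripts, log2 ratios were smaller for IFI27, at 0.68, and larger in size for the lower genes, at -1.09 against -0.47 for ISG15 and -1.26 against -0.62 for IFI35.

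The other clusters followed the libraries in part. Cluster 1, led by SLC26A2, CXCL1 and TNFRSF11B, held 163 and 499 cells. Cluster 4 held 194 and 9 cells and cluster 7, led by CA12 and MGP, 101 and 4. A cluster mostly of 1 library may be that library rather than a cell state. Cluster 5 was led by nuclear copies of mitochondrial ribosomal RNA, such as MTRNR2L12 (653 CPM inside and 33.6 CPM outside), and by the mitochondrial gene MT-RNR2 itself. MT-RNR2 was far more abundant, at 102779 CPM inside and 12063 CPM outside. The copies share sequence with it, so their counts are uncertain. Cluster 5 had a median of 917 UMIs and 15.1% mitochondrial UMIs, and held 107 and 92 cells. The G2/M-like cluster 3, led by NUF2, UBE2C and TOP2A, held 14.3% (12.2% to 16.6%) of cells at 0 mM and 16.8% (14.5% to 19.2%) at 2 mM. This order turned at other clustering settings; at resolution 0.25 the shares were 30.5% and 16.9%. Cluster 4 also held many G2/M transcripts, with 8072 CPM of the list against 2141 CPM in the 0 mM cells of cluster 1.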

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

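Of the data outside the comparisons, the 9 barcodes of the 2 mM library below the cell minimum held 4181 UMIs, whereas 0 UMIs of the 0 mM library lay in such barcodes. The shallowest deposited barcode had 2 UMIs at 2 mM and 774 UMIs at 0 mM. With all deposited barcodes included, 210 genes were at least 1.5-fold higher and 139 lower. With 1 library per dose, the search for outlying samples could not be made.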

How the results depend on the processing

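The alternatives that leave out clusters, barcodes ending in an uncalled base or interferon-like clusters, that merge barcodes, that use 10 cycle UMIs or that count interferon marker UMIs were chosen after seeing the data. Of 2230 values of 203 named genes under the alternatives, 1957 stayed within the counting interval of the main ratio, 270 lay outside it in an unaltered direction or for genes within 1.5-fold, and 3 turned direction. These 3 were the log2 ratios of CTGF (0.27), MT1X (0.0135) and PSAT1 (-0.18) in cells with at most 1 cycle UMI, a set of 118 and 141 cells; the cause was not tested. Of 390 list values, 375 stayed within the main interval. None of the 5 lists outside the random range turned sign under these alternatives. Within groups of cells 3 of them did: G2/M was 0.11 in the pooled interferon-like clusters, NF-kB -0.06 in cluster 1 and nuclear-retained long RNAs 0.38 in cluster 5. Lists with medians nearer 0 did, such as complex I (-0.05) and endoplasmic reticulum folding (-0.04) with TMM factors and immediate early genes (0.04) in cells with at most 1 cycle UMI.

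Genes at least 1.5-fold higher and lower were 441 and 287 in cells with at most 1 cycle UMI (2-fold 109 and 71). That set has fewer UMIs and is selected by cycle transcripts, and the cause of the higher counts was not tested. They were 566 and 313 at 20 CPM (141 and 50), 82 and 71 at 100 CPM (26 and 12), and 1042 and 544 with no CPM minimum (297 and 105). Genes compared were 7216, 2135 and 9941 in this order. At the lower minimums the counts rose by more than the number of genes compared. TMM factors gave 223 lower genes (38 at 2-fold), and leaving out interferon-like clusters gave 218 (44). The G2/M median was -0.20 without the top 5% of barcodes, -0.25 with at most 1 cycle UMI, by selection, and -0.60 without interferon-like clusters. The median of the list named nuclear-retained long RNAs was -0.56 with TMM factors and -0.52 with at most 1 cycle UMI. Except where stated, causes were not tested.

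The difference in G2/M-like cluster shares, 2.45 points higher at 2 mM, became -13.6 at resolution 0.25, -1.05 at resolution 1, -11.9 in thinned cells and -4.01 without the S and G2/M genes. The distance between the cluster shares of the libraries, 44.9 points, was 27.3 at resolution 0.25 and 58.6 at resolution 1. The S-phase difference was -18.7 points in unthinned cells, where depth differs. The G2/M difference of -9.28 points was -13.6 with barcodes merged. Median UMIs were 3787 and 2933 with barcodes merged, and 3082 at 2 mM with at least 1000 UMIs. Depth limits the scarce genes: 3 counts are 0.681 and 0.919 CPM. No paired analysis was possible because each dose had 1 library.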

Other observations

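In the paragraphs on explanations below, the tests of depth per cell and of chance neighbours among barcodes were chosen after the result was seen. The rule for judging a list's median was also tightened after its first use, which turned the verdict on the barcodes with the most UMIs from argued against to open. Several genes of antigen presentation by class II molecules and of the acute phase were chosen after their values were seen, because they were higher at 2 mM. No list of such genes was fixed beforehand, so they do not show that these classes of genes differ as a whole. HLA-DRA had 578 and 1216 CPM (ratio 2.10, 2.00 to 2.21), HLA-DRB1 a ratio of 2.49, HLA-DPB1 one of 2.42 and HLA-DMB one of 1.78. B2M, the light chain gene of class I molecules, had a ratio of 1.10. SAA1 had 1402 and 3381 CPM (ratio 2.41), the complement gene C3 a ratio of 2.52 and the fibronectin gene FN1 one of 1.92. PTX3 (0.472), HMGA1 (0.517) and SERPINE2 (0.518) were lower.

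Inside single clusters, a comparison added after seeing the data, hypoxia targets had a median log2 ratio of 0.64 in the interferon-like cluster 2, with 17 of 17 genes above 1. It was 0.31 in cluster 1, with 15 above 1, 0.12 in cluster 3 and 0.01 in cluster 5. Glycolysis genes had 0.33, 0.26 and 0.12 in clusters 1, 2 and 3 and -0.28 in cluster 5, whereas over all cells the median was -0.07. NRF2 targets were below 0 in clusters 1, 2, 3 and 5, at -0.20, -0.30, -0.19 and -0.27. The cause of these differences was not tested. Of the leading genes of cluster 2, IFNL1, which encodes a type III interferon, had 425 CPM inside the cluster and 10.8 CPM outside it. The chemokine genes CCL5 (643 and 40.2 CPM) and CXCL10 (540 and 46.4 CPM) were also higher inside. These levels, like those of IFNL1, are means of the CPM of the 2 libraries.

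The lower G2/M genes at 2 mM could reflect depth, low-quality barcodes or doublets. Depth per cell is argued against, since at 1000 UMIs per cell the ratio of mean G2/M UMIs was 0.813 (0.780 to 0.846). That interval leaves out the spread between cells and is too narrow. In shares of cells the difference was -9.28 points (-16.0 to -2.52) at 1000 UMIs, though its interval included 0 at 2000 UMIs. Barcodes with a high mitochondrial share are argued against too, as the median log2 ratio was -0.43 (-0.55 to -0.32) without them. Barcodes with the most UMIs stay open, because without them the median was -0.20 (-0.32 to -0.12), and dividing cells are also large. In cells picked by alternate genes of the list, the remaining genes had a median of -0.30 (-0.40 to -0.24). Such picked cells also include some outside G2/M, and their share may differ between the libraries. The value therefore cannot decide whether fewer G2/M cells alone explain the lower genes, which stays open.

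The higher levels of these chosen acute phase and class II genes might come from other cells or from a larger cell subset. Leukocytes are argued against, since PTPRC, LYZ, TYROBP and CD3E together had 7 UMIs at 0 mM and 3 at 2 mM, a difference of -0.0779% of that of CD74. A larger share of an unaltered subset would leave ratios near 1 within subsets. The median ratio of 10 genes was 2.30 in interferon-like, 2.47 in G2/M-like and 2.66 in other clusters. These were SAA1, SAA2, LCN2, C3, CD74, HLA-DRA, HLA-DRB1, HLA-DPB1, HLA-DRB5 and the chemokine gene CXCL1, chosen because they were higher in these same cells. As the first and last group hold different clusters in each library, and cluster 1 (163 and 499 cells) has some such genes among its leading genes, single clusters were compared too: the median ratio was 2.28 in cluster 1, 2.80 in cluster 2, 2.47 in cluster 3 and 2.53 in cluster 5, with 7, 8, 10 and 6 of the 10 genes past 1.5-fold and lowest ratios of 1.17, 1.36, 1.60 and 0.724. Free RNA of abundant transcripts could raise such genes in every cluster, and it was not measured. These values therefore argue against a larger unaltered subset only if free RNA adds little. An effect of metformin, drift between separately kept cultures, and differences in preparing 2 libraries stay open as untested.

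Barcodes of 12 bases that differ by 1 base were far more frequent than chance gives, with 100 pairs at 0 mM and 179 at 2 mM, an excess of 93.3-fold and 170-fold, which argues against independent barcodes. All 100 pairs at 0 mM and 149 at 2 mM differed at base 12. Members of a pair shared a cluster in 97.0% and 91.6% of pairs, against 16.7% and 25.3% for random pairs of the same barcodes, an excess of at least 66.4 points. Many such pairs may therefore be 1 cell read under several barcodes, which would lower the number of cells by 69 and 108 and make the intervals of cell shares too narrow.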
